A study of Mus musculus with 2 samples.

How the data were processed

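RNA was sequenced from the olfactory epithelium, the nasal tissue that holds the olfactory sensory neurons, of adult C57BL/6 mice. Total RNA was isolated with Trizol and made into TruSeq libraries, per the labels' protocols. The series has 2 samples. Both titles and both genotype labels call them wild type, and both were therefore placed in 1 group. Their description fields differ, however, and name the first wt and the second 3bko. What 3bko stands for is not given in the sources used here.

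The table analysed here holds olfactory receptor (Olfr) genes only, in 1112 entries with 1110 distinct names. It has a locus, a test status and a single FPKM value (fragments per kilobase of gene model, scaled to the total of mapped fragments) per entry, per the file headers. The FPKM values were deposited by the authors. Reads were aligned with TopHat2 and Bowtie2 to the mouse build mm9 and quantified with Cuffdiff, per the submitters' processing notes, which give no versions or roles. The gene annotation, the read length, the treatment of reads that match several genes and the number of mapped reads are not given in the sources used here. Every row carries the words wt and 3bko in its 2 sample columns, per the file headers, and the table does not state whether the FPKM belongs to the first library, to the second or to both. The value was therefore treated as the authors' single value, with no standard deviation and no n. No comparison between the 2 libraries and no measure of replicate error could be made, and the planned values per library became 1 value per gene. Tests below run across genes. Genes are not independent replicates, and the p-values describe this one set of values.

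The values were tested for steps of whole reads. Among 185 low entries with coding-only gene models, 28.6% lay within 0.1 of a whole read at the best of the steps tried. By chance 20% would do so at a single fixed step. The best step was picked on these same entries, so its own chance share is higher and was not computed. Most entries were not near a whole read, so reads could not be recovered and the sequencing depth is unknown. No counting interval or detection limit is therefore given. Status was OK for 909 entries and NOTEST for 203. The NOTEST entries ended at an FPKM of 0.324 and the lowest OK entry had 0.0889.

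Locus starts in the table count from 0, and 1 was added to print them. Of 858 loci shorter than 1000 bp, 829 (96.6%) had a length that is a multiple of 3. For 759 of the 1112 entries (68.3%) the locus was as long as the coding sequence in GENCODE M21, with or without the stop codon. For those entries the authors' FPKM covers coding sequence and not the untranslated regions. All coordinates are mm9 and come from the deposited table. GENCODE M21 and the RefSeq gene table are on GRCm38 and were used for names, gene types and transcript features, never for coordinates. By symbol, 1095 entries matched the RefSeq table, 12 more matched by an older symbol and 5 did not match. GENCODE held 1105 of the entries.

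The gene lists, the main tests and most alternatives were fixed before the data were examined. The 3 comparisons of exon numbers, and the alternatives named as such in the closing section, were added after the values were seen. Class I receptors were those with a MOR family name from 1 to 42 among their synonyms, and all others were class II. Without such a synonym (23 entries) the class was set by symbol number. Conflicting synonyms occurred for 2 entries, and both were kept in class I. One of them, Olfr1137, lies on chromosome 2. Receptor families were the MOR families. Pseudogenes were symbols ending in ps or RefSeq pseudogenes. Genomic clusters were runs of Olfr loci with less than 1 Mb between neighbours. A list of 17 receptors with prior functional study and the list of 3 neighbours of the H enhancer element were also fixed. Lists of cell type markers had been fixed too, and the table holds none of their genes. The text names the 12 entries with the highest FPKM, the 17 studied receptors and up to 2 of the highest entries in each class, family or cluster it describes. Other genes are named only where they share a value or, as Olfr1137, have conflicting synonyms, and were chosen after their values were seen.

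Differences between lists were tested as differences in median log2(FPKM + 0.1) with a two-sided permutation test across genes (100000 resamples), so 1e-05 is the smallest p these permutations can give. The list of 3 genes was tested by exact enumeration. A log2 difference on this scale understates the change of low genes. Families and clusters of at least 10 entries were compared with the Kruskal-Wallis statistic and 100000 permutations, and each was then tested against all other entries. Correlations with transcript features used the longest coding transcript of each gene in GENCODE M21, or its longest transcript where none is coding. A length of an untranslated region was used only where one is annotated. Benjamini-Hochberg adjustment was applied within each family of tests, with a threshold of 0.05. Intervals are 95% bootstrap intervals over genes with 2000 draws. The share of a coding sequence's 50-mers found in no other Olfr transcript of GENCODE M21 was used as a measure of how far reads can be told apart. Coding sequences were cut from the transcripts at the annotated coding exons and the stop codon, for 1101 entries, of which 1100 begin with ATG. GC content was taken over the same sequences. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

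The tests were tested on simulated data made from the 1112 values with shuffled gene labels. In 100 simulations each, a planted shift of the class I list was called in 68% at 0.5 log2 units and in 100% at 1 log2 unit, against 7% with no shift. Family differences with an SD of 1 log2 unit were called in 100% of simulations over 490 genes, against 7% with none. A planted correlation of 0.2 was called in 100%, against 3% with none. The shuffling removes any similarity of neighbouring genes. These rates therefore do not cover groups set by genomic position, such as class I, clusters and families within 1 cluster. False calls may be more frequent for such groups. Alternatives were other pseudocounts, a filter on low FPKM, means for medians, leaving out pseudogenes, other limits for clusters and families, and other comparison sets for class I. Means over libraries and leaving out 1 library were planned and could not be run on a single value per gene.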

Results

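Olfactory receptor transcripts were profiled by RNA-seq in the olfactory epithelium of adult C57BL/6 mice, to describe the transcriptome of the Olfr genes, the large family of odorant receptors. The series holds 2 samples, both titled and genotyped as wild type, of which the second is described as 3bko. The deposited table gives 1 FPKM value per Olfr entry for 1112 entries on 17 chromosomes. It cannot be tied to either sample, so the values below are the authors' single values, without replicates or replicate error. Depth is unknown.

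Receptor transcripts were detected at low levels across most of the repertoire. The median FPKM was 1.09, with an interquartile range of 0.377 to 3.00 and a highest value of 57.2. Of the 1112 entries, 584 (52.5%) had an FPKM of 1 or more, 159 (14.3%) reached 5, 60 (5.40%) reached 10 and 14 reached 20. Another 9 entries were listed at 0. Expression was unequal across receptors, with a mean FPKM of 2.66 above the median of 1.09, yet was not held by a few. The top 10 entries held 11.7% of the summed Olfr FPKM and the top 100 held 47.0%. The highest 113 of the 1112 entries held 50% of the sum.

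The highest value was that of Olfr533 (chromosome 7, 147652102 to 147653064, mm9), at an FPKM of 57.2. It was followed by Olfr727 (chromosome 14, 50746228 to 50747262), at 55.4, Olfr166 (chromosome 16, 19486933 to 19487871), at 36.5, and Olfr1507 (chromosome 14, 53109610 to 53115370), at 36.0. Olfr1507 is the MOR28 receptor, whose gene lies beside the H enhancer element. The next entries were Olfr6 at 28.7, Olfr1384 at 27.5, Olfr536 at 26.8, Olfr1301 at 26.3, Olfr15 at 26.0, Olfr741 at 24.5, Olfr1364 at 23.4 and Olfr1348 at 21.9. All 12 of these receptors are class II genes, and they lie on 6 chromosomes. The share of 50-mers of the coding sequence found in no other Olfr transcript was 100% for Olfr6, Olfr1301, Olfr15 and Olfr1364, and lowest for Olfr166 (56.5%) and Olfr1348 (51.7%), whose values are uncertain where reads are shared. Without replicates, the order of neighbouring values such as Olfr533 and Olfr727 could not be tested.

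Receptors with prior functional study ranged from the top of the list to near its bottom. Of the 17 fixed before the data were examined, 13 had an FPKM of 1 or more and 4 were below it. Apart from Olfr1507 and Olfr15, the highest were Olfr17 (the P2 receptor) at 8.77 and Olfr43 at 7.11. Olfr1509, a receptor for the mouse urine odorant MTMT, had an FPKM of 4.02, the muscone receptor Olfr1440 had 3.99, and Olfr1508 (MOR10) had 3.15. The eugenol receptor Olfr73 had 2.49, the octanal receptor Olfr2 (I7) had 2.17, Olfr62 had 1.52 and the lyral receptor Olfr16 (MOR23) had 1.38. The acetophenone receptors Olfr160 (M72) and Olfr151 (M71) lie on the same stretch of chromosome 9 and had 1.79 and 0.164. Olfr151 has the status NOTEST and is typed as a pseudogene in the RefSeq table, so it is also counted among the pseudogene entries. Only 59.8% of the coding 50-mers of Olfr151, 59.7% of those of Olfr160 and 26.3% of those of Olfr43 were unique among Olfr transcripts, so their values are uncertain. The class I members were Olfr544 at 1.02, Olfr78 at 0.866, Olfr545 at 0.365 and Olfr558 at 0.270, with 63.7% of the coding 50-mers unique for Olfr544 and 61.5% for Olfr545. The value of Olfr78 is shared with Olfr560, which has the same locus in the table, and belongs to neither alone.

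The median FPKM of the studied receptors was 2.17 against 1.07 for the other entries. The difference of 0.95 on the log2(FPKM + 0.1) scale did not pass the test (95% interval -0.03 to 1.87, permutation p = 0.122, adjusted p = 0.237 over 4 list comparisons). The 3 neighbours of the H element, Olfr1507, Olfr1508 and Olfr1509, had a median of 4.02 against 1.08, which did not pass the test either (exact permutation p = 0.178, adjusted p = 0.237).

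Class I receptors, the fish-like odorant receptors, had lower values than class II receptors. The median FPKM was 0.467 (interquartile range 0.220 to 0.874) over 127 class I entries and 1.27 (0.432 to 3.39) over 985 class II entries, a 2.71-fold higher median in class II. An FPKM of 1 or more was found for 26 class I entries (20.5%) and 558 class II entries (56.6%). None of the class I entries reached 10, against 60 of class II, and none was among the 100 highest. The highest class I values were those of Olfr613 (chromosome 7, 110698882 to 110704018), at 5.47, and Olfr672 (chromosome 7, 112144478 to 112145416), at 4.31. Class I made up 11.4% of the entries and 2.99% of the summed FPKM. The median difference was -1.27 on the log2(FPKM + 0.1) scale (95% interval -1.67 to -1.03). It passed the two-sided permutation test across genes (p = 1e-05, the smallest these permutations can give, adjusted p = 4e-05). Its size depended on the pseudocount, at -0.63 with a pseudocount of 1 and -1.42 with 0.01.

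**Figure D1:**
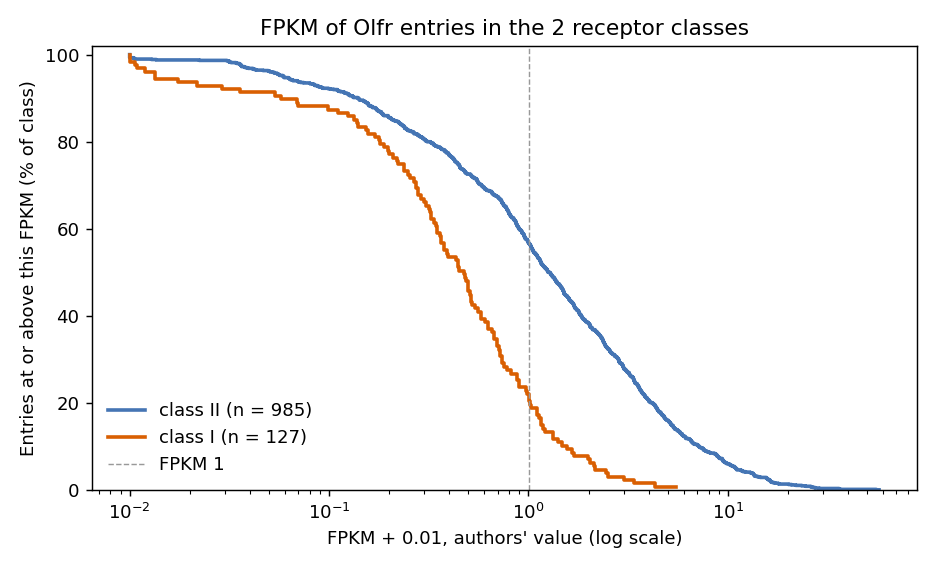
Percent of entries of each class (vertical axis) at or above a given FPKM (horizontal axis, log scale, 0.01 added) for 127 class I and 985 class II entries; the dashed line marks an FPKM of 1. At that line 20.5% of class I and 56.6% of class II entries remain.

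Of the 127 class I entries, 124 lie in a single genomic cluster, on chromosome 7 from 109.6 to 112.5 Mb, which holds no class II entry. Class and position therefore cannot be told apart within these data. The class II cluster on chromosome 9 from 37.5 to 40.0 Mb had a median of 0.465 over 99 entries, against 0.472 in the class I cluster, and is named here because its median was the lowest, so the 2 were not tested against each other.

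Levels differed between genomic clusters. In 21 clusters of at least 10 entries, with 1015 entries in all, the Kruskal-Wallis statistic was 188 (permutation p = 1e-05). Tested one by one against all other entries, 8 clusters were higher and 2 were lower, the latter being the class I cluster and the chromosome 9 cluster named above (permutation test, adjusted p = 0.00021 each). In the chromosome 9 cluster the highest values were those of Olfr912 at 6.08 and Olfr972 at 5.30. The highest of these 21 clusters lies on chromosome 7 from 147.3 to 147.9 Mb. All 19 of its entries had an FPKM of at least 1, with a median of 5.35 and with Olfr533 at 57.2 and Olfr536 at 26.8 (adjusted p = 0.00042, permutation test). It holds 1.71% of the entries and 6.62% of the summed FPKM. Chromosome 11 from 48.9 to 49.4 Mb followed with a median of 4.14 over 18 entries, led by Olfr1384 at 27.5 and Olfr1392 at 9.64 (permutation test, adjusted p = 0.0047). Only 76.7% of the coding 50-mers of Olfr1384 and 50.5% of those of Olfr1392 were unique among Olfr transcripts, so their values are uncertain. The cluster on chromosome 14 from 50.5 to 53.1 Mb, with Olfr727 and Olfr1507, had a median of 2.56 over 36 entries and held 8.30% of the summed FPKM (permutation test, adjusted p = 0.0125). Of the 8 higher clusters, 6 kept the call among entries at FPKM 0.1 or more. Neither the calls of single clusters nor those of single families below were tested for reads shared between similar genes. The largest cluster, 225 entries on chromosome 2 from 85.2 to 90.4 Mb, had a median of 1.11 and did not differ past the threshold from the rest (permutation test, adjusted p = 0.86). Its highest entries were Olfr1110 at 20.1 and Olfr1261 at 16.0.

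**Figure D2:**
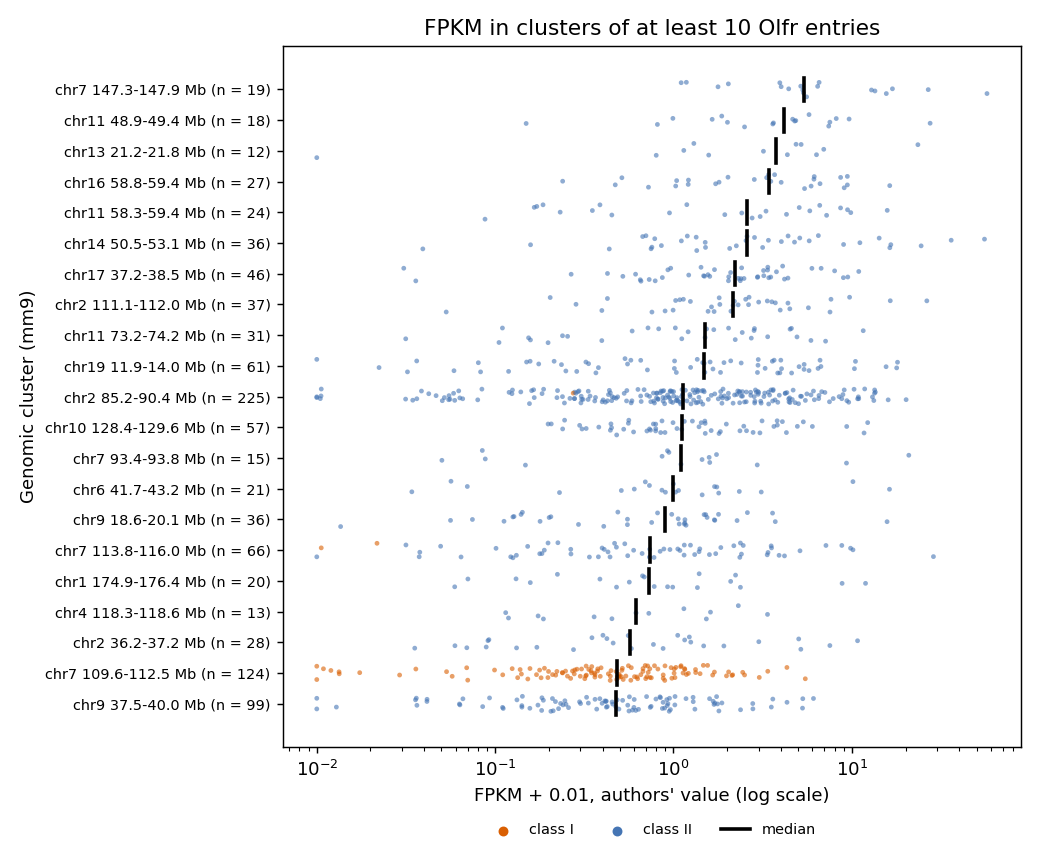
FPKM of each entry (points; horizontal axis, log scale, 0.01 added) in the 21 genomic clusters of at least 10 Olfr entries (vertical axis, mm9 positions), ordered by their median (black bars). Medians run from 0.465 on chromosome 9 to 5.35 at the far end of chromosome 7, and the class I cluster has 0.472.

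Receptor families differed as well. Over 30 MOR families of at least 10 entries (490 entries) the Kruskal-Wallis statistic was 168 (permutation p = 1e-05). Tested one by one, 4 families were higher than the other entries. MOR253 had a median of 5.46 over 10 entries and included Olfr53 at 16.9 and Olfr541 at 15.6 (adjusted p = 0.018, permutation test). Of these entries, 9 lie in the highest cluster, on chromosome 7 from 147.3 to 147.9 Mb, so this call is not separate from that of the cluster. MOR103 had 4.42 over 17 entries and included Olfr6 and Olfr1348 (permutation test, adjusted p = 0.0129). MOR231 had 4.05 over 14 entries, with Olfr1240 at 10.3 and Olfr1247 at 9.37 (permutation test, adjusted p = 0.0307). MOR256 had 3.07 over 50 entries, with Olfr1384 and Olfr15 highest (permutation test, adjusted p = 0.0009). Lower than the rest were MOR204, with a median of 0.419 over 31 entries, and MOR136, with 0.277 over 14 entries (permutation test, adjusted p = 0.0351 each). The highest MOR204 entries were Olfr491 at 5.11 and Olfr472 at 3.90, and those of MOR136 were Olfr342 at 5.17 and Olfr339 at 5.03. For MOR136 the 95% interval of the median difference ran from -2.76 to 0.14. With a pseudocount of 1, neither MOR204 nor MOR136 passed the threshold, while all 4 higher families did. The class I families MOR32 and MOR31 had medians of 0.244 and 0.646 and did not pass the threshold (permutation test, adjusted p = 0.0549 and 0.438). MOR32 did pass it with a pseudocount of 0.01, among entries at FPKM 0.1 or more and without pseudogenes. Of the 30 families, 20 lie in a single cluster, so family and position are largely shared. The MOR103 entries are spread over 7 clusters and the MOR256 entries over 6.

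Entries classed as pseudogenes by symbol or RefSeq type did not differ past the threshold from the other receptors. Some of them have an annotated coding sequence in GENCODE M21 and some have none, so the list is mixed. The median FPKM was 0.787 over 27 pseudogene entries and 1.09 over 1085 others, a difference of -0.42 log2 units (95% interval -1.79 to 1.00, permutation p = 0.353, adjusted p = 0.353). The direction turned to 0.65 when entries below an FPKM of 0.1 were left out. Among pseudogenes, Olfr856-ps1 (chromosome 9, 19461483 to 19463124) at 15.7 and Olfr1372-ps1 (chromosome 11, 51968378 to 51971409) at 13.6 were the highest.

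The series title concerns features of receptor mRNAs, and FPKM was therefore set against transcript features annotated in GENCODE M21. Receptors with more annotated exons had higher FPKM. The median was 0.0891 for 120 genes with 1 exon, 1.05 for 628 genes with 2 exons, 1.59 for 272 genes with 3 and 2.42 for 85 genes with 4 or more. Of the single-exon genes, 9 reached an FPKM of 1, 88 had the status NOTEST and 68 had no annotated untranslated region on either side. The difference between genes with 1 exon and those with 2, tested after the values were seen, was -2.60 log2 units (95% interval -2.98 to -2.31, permutation p = 1e-05, adjusted p = 1e-05 over 3 comparisons of exon numbers). The single-exon median lies below the pseudocount of 0.1, so the size of this difference depends on the pseudocount. Across 1105 genes, Spearman's rho of FPKM with exon number was 0.381 (95% interval 0.326 to 0.433) and Pearson's r was 0.372 (permutation p = 1e-05 each, adjusted p = 1.67e-05 over 5 features). Among entries at FPKM 0.1 or more rho was 0.25. It was 0.241 among the 1020 genes with both untranslated regions annotated.

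A longer 5' untranslated region (UTR) also went with higher FPKM. The median FPKM was 0.797 in the tercile of genes with annotated 5' UTRs of 3 to 194 nt, 1.13 at 195 to 441 nt and 2.31 at 442 to 3411 nt. Across 1030 genes rho was 0.337 (95% interval 0.280 to 0.391) and r was 0.277 (permutation p = 1e-05 each, adjusted p = 1.67e-05). Transcript length gave rho = 0.301 and r = 0.264 over 1105 genes (permutation p = 1e-05 each, adjusted p = 1.67e-05), and rho fell to 0.165 among entries at FPKM 0.1 or more. The 3' UTR length gave a smaller rho of 0.0906 over 1023 genes (permutation p = 0.00352, adjusted p = 0.0044; r = 0.0716, permutation p = 0.0222). Coding GC content gave rho = 0.0611 over 1101 genes (permutation p = 0.0429, adjusted p = 0.0429; r = 0.0898, permutation p = 0.00318), and GC content of the whole transcript gave the opposite direction, with rho = -0.102 (permutation p = 0.00061). Neither 3' UTR length nor coding GC content passed the threshold among entries at FPKM 0.1 or more, where rho was 0.0457 and 0.0378. All of these relations are across genes of 1 set of values, and annotated lengths depend on the transcripts behind the annotation. The features come from the same annotated transcript of each gene, and transcript length includes the untranslated regions. They therefore overlap, and none was adjusted for another.

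**Figure D3:**
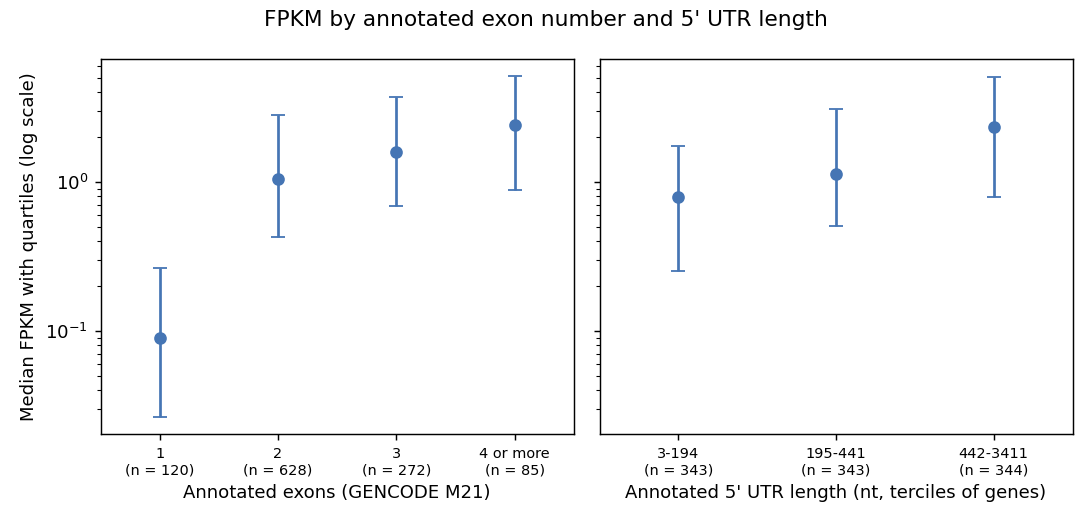
Median FPKM (points, log scale) with the lower and upper quartiles (bars) of Olfr genes by annotated exon number (left) and by terciles of annotated 5' UTR length in nt (right). Medians run from 0.0891 with 1 exon to 2.42 with 4 or more, and from 0.797 to 2.31 across the terciles.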

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

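The class difference and the relations with exon number, 5' UTR length and transcript length kept their direction and stayed past the threshold under each alternative run. The Kruskal-Wallis tests over families and over clusters, which have no direction, also stayed past it. The transcript features overlap, as described above, and are not separate lines of evidence. The alternatives with other comparison sets for class I, without the families or the cluster of class I, without entries that share a value or with these counted once, and for the calls of single families and clusters were chosen after seeing the data. The number of families lower than the rest went from 2 to 5 with a pseudocount of 0.01, to 0 with a pseudocount of 1 and to 5 without pseudogenes; the cause was not tested. Among entries at FPKM 0.1 or more it was 2, namely MOR204, as in the main call, and MOR32. MOR32, MOR162 and MOR177 were the families gained both with a pseudocount of 0.01 and without pseudogenes, and MOR233 was gained as higher without pseudogenes. In the main call each of these gained families had an adjusted p of 0.0549 (permutation test), just above the threshold. The 4 higher families and the 2 lower clusters were called under all 4 of these settings. Of the 8 higher clusters, 6 remained called among entries at FPKM 0.1 or more and 7 without pseudogenes. Those lost were on chromosome 11 from 58.3 to 59.4 Mb under both, and on chromosome 2 from 111.1 to 112.0 Mb under the first. The class difference ranged from -0.63 with a pseudocount of 1 to -1.42 with a pseudocount of 0.01, and was -1.39 against the class II entries of chromosome 7 alone. The number of detected entries followed its threshold and was 1016 at an FPKM of 0.1, 159 at 5 and 1103 above 0. Among entries at FPKM 0.1 or more, the pseudogene difference reversed to 0.65 (permutation p = 0.189), rho with 3' UTR length was 0.0457 (permutation p = 0.153) and rho with coding GC content was 0.0378 (permutation p = 0.231). The filter itself, which drops 96 of the low entries, made these changes and no further cause was tested. The filter also lowered rho with exon number to 0.25 and with transcript length to 0.165. With a pseudocount of 1, Pearson's r with 3' UTR length was 0.0474 and no longer past the threshold. With GC content of the whole transcript in place of the coding sequence, an alternative also chosen after seeing the data, rho reversed to -0.102 (permutation p = 0.00061); the cause was not tested. The pseudocount cannot change a rank correlation, so it says nothing about the stability of rho. No paired analysis was possible because the samples form 1 group and the table holds 1 value per gene. For the same reason the planned differences between the 2 libraries, the list differences between them and the values without replicate 1 or 2 were not run. Depth is unknown, so how far counting error limits the low values could not be given. Entries listed at 0 or marked NOTEST are the least certain.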

Other observations

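All tests in this part but one had their prediction written before their result was seen. The exception is the comparison of gene models in the paragraph on exon number. The tests that use 50-mers or GC content had first been run on whole transcripts, and the values given are those on coding sequences under the same predictions. The patterns themselves were found in the same values, so the statements below are hypotheses.

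The lower FPKM of class I receptors was weighed against technical causes. The median difference was -1.32 log2 units (95% interval -1.93 to -0.89) among the 494 genes with at least 95% unique coding 50-mers. Over all entries it was -1.27. This argues against reads that match other Olfr transcripts exactly over 50 nt as its cause. The read length is unknown and mismatches were not allowed for, so reads shared in other ways stay open. Among the 759 entries whose locus is the coding sequence alone the median difference was -1.37 (95% interval -1.77 to -1.06). This argues against gene models that span introns or untranslated regions. In a linear model with coding GC content and coding length the class coefficient was -1.45 (95% interval -1.70 to -1.20), against an unadjusted mean difference of -1.32. Genomic position stays open, since the class I cluster holds 0 class II entries. Fewer neurons choosing a class I gene, or less transcript in each such neuron, may both be behind the values, and FPKM of whole tissue does not separate them.

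Genes next to each other had similar FPKM. Pearson's r of log2(FPKM + 0.1) over 1062 adjacent pairs within clusters was 0.363 (permutation p = 0.0001, the smallest these permutations can give). When FPKM was permuted within clusters, r had a median of 0.191 and a 95% range of 0.142 to 0.239. The permutation p-values of this paragraph are one-sided, for an r at least as high. Among the 299 pairs with at least 95% unique coding 50-mers in both genes, r was 0.292 (permutation p = 0.0123). The permuted range there was 0.0641 to 0.277. This argues against reads that match both neighbours exactly over 50 nt as the only cause. Reads shared in other ways stay open. Among the 136 such pairs of different MOR families r was 0.203, inside the permuted range of 0.0323 to 0.352 and close to its median of 0.197 (permutation p = 0.471). A value in that range had been set beforehand as what shared reads would give, yet the pairs are few and the range is wide, so shared reads are not excluded and whether similarity of neighbours needs a shared family stays open. A candidate explanation is regulation shared along a stretch of a cluster, which was not tested further.

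The relation of FPKM with annotated exon number was not a difference between receptor classes, since rho was 0.384 among class II genes and 0.381 over all genes. Among the 1020 genes with both untranslated regions annotated rho was 0.241 (permutation p = 1e-05), lower than over all genes and still past the threshold. That value lies between the limits set beforehand for and against missing untranslated regions as the cause, so the test could not decide. Leaving such genes out also drops at least 68 of the 120 single-exon genes, which narrows the range of exon numbers. Those 68 have no annotated untranslated region on either side, and single-exon genes with only 1 are dropped too. An annotation built from transcripts that are found more easily for abundant genes may give the same relation, and the transcripts behind GENCODE M21 were not used here. In the authors' own gene models, entries with a locus other than the coding length had a median 0.057 log2 units above the coding-only entries (95% interval -0.22 to 0.30, permutation p = 0.728), which does not exclude it for GENCODE.

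Within clusters of at least 10 entries, Spearman's rho of FPKM with the distance to the nearer cluster end was -0.165 over 1014 loci, against a range of -0.154 to -0.0749 when FPKM was permuted within clusters (permutation p = 0.0151, not adjusted for other tests). FPKM was thus slightly higher towards cluster ends, by a margin small beside the part set by differences between clusters. Permuting FPKM within clusters also breaks the similarity of adjacent genes described above. The permuted range may therefore be too narrow for a trend along a cluster, and the test cannot decide whether there is one.

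Several entries share 1 value. Olfr247 is listed on 2 loci of chromosome 10 with an FPKM of 0.785 at each, and Olfr1506 on 2 loci of chromosome 2 with 1.04 at each. Olfr560 and Olfr78 share a locus and the value 0.866. Another 3 entries name 2 genes each, with FPKM values of 5.58 for Olfr286 and Olfr287, 1.70 for Olfr242 and Olfr27, and 0.369 for Olfr1433 and Olfr1434. These genes were named because they share a value.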
